A study of Mus musculus with 15 samples.

How the data were processed

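Liver RNA of mice labelled as adult males aged 3 months was measured on Affymetrix mouse arrays, 1 array per mouse, in 15 mice. RNA was extracted with TRIZOL and cleaned on RNeasy columns before biotin labelling, per the labels' protocols. The 5 groups of 3 were Z-on and M-on (human alpha1-antitrypsin Z or M expressed, no doxycycline), Z-off and M-off (doxycycline at 40 µg per mL from conception, expression shut off) and nontransgenic littermates without doxycycline. Groups and replicate numbers were taken from the labels.

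The deposited values are probe set intensity values on a linear scale, from 0 to 22995.4, and RMA, with no version given, is the only tool that the submitters' processing notes name. The deposited values were not in log2 units. Their 2% trimmed mean was 150.06 to 150.08 on every array while their medians differed, and values of 0 occurred, unlike RMA output, so they were treated as scaled linear signals. The scaling that made them is not given in the sources used here. Before the tests the constant 16 was added and log2 taken. The constant was chosen after the values were seen and before any call at another constant.

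Of 22690 probe sets, 64 were array controls, 20380 had 1 gene, 691 several genes and 1555 none, by the table of probe genes. For each gene the probe set with the highest mean over all arrays, among those with 1 gene, was used, and 4956 genes had more than 1. Symbols were checked against RefSeq gene names of GRCm38.p6, where 20351 probe sets matched and 0 symbols changed. The genome build of the array is not given in the sources used here, so no coordinates are printed and genes are named by symbol.

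Differential expression was tested with limma 3.58.1 in R 4.3.3. A linear model with 1 mean per group was fitted to all 15 arrays for 12393 genes, with 10 residual degrees of freedom and 3.89 prior degrees of freedom from empirical Bayes. The 9 contrasts were Z-on minus Z-off, M-on minus M-off, Z-on minus M-on, Z-on and M-on minus littermates, Z-off minus M-off, Z-off and M-off minus littermates, and the difference of the 2 on-off changes (interaction). Tests were two-sided, p was adjusted by Benjamini-Hochberg within a contrast, and genes under 0.05 were called. Changes are given on the log2 scale with the standard error (SE) of the contrast, and signals as means ± SD of linear values over 3 arrays.

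The 40 gene lists held 1338 entries, of which 1152 were measured, 20 through older symbols. They were written before the data were examined and tested with camera of limma at a preset correlation of 0.01, adjusted over 40 lists and 9 contrasts (360 tests), and again with the correlation estimated from the residuals. For counts adjusted over the list alone, Benjamini-Hochberg was applied to the list's members only.

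Genes were named by a rule set before the data were examined. For the on-off contrasts of both lines, Z-on minus M-on and Z-on minus littermates, these were the 12 largest rises and 12 largest falls among called genes whose 3 arrays of one group all lay beyond the other 3. For the other contrasts they were 4 and 4, without the condition on arrays for the interaction, and clone or predicted-gene symbols were passed over. Up to 4 called members of a described list with the smallest adjusted p were named, or up to 2 with the smallest p where none was called. Rgs16, Serpina1 genes, Hspa5, Dnajb9, Xbp1 and Ddit3 were named throughout. Xist, Eif2s3y and the control probe sets were read per array after the values were seen. Principal components were computed from the log2 values, and figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

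Alternatives chosen before the data were examined were a fit of only the groups compared, genes above the 40th percentile of mean signal (8181 genes), all probe sets, quantile normalization, an intensity trend with robust spread, array weights, replicate number as a block, and each array left out in turn. Chosen after the data were seen were constants of 1 and 64, leaving out arrays M-on 1 and 2 or M-on 2 and 3, and quantile normalization for the lists. The genes of one group alone were counted again under these constants and after quantile normalization.

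The procedure was tested on simulated data with the real genes' means and spreads. For Z-on minus M-on over 12393 genes it recovered 16.4% of genes changed by 0.585 log2 units, 67.2% at 1 and 100% at 2, and called 0.0492% of unchanged genes. For the interaction the shares were 1.49%, 20.9%, 95.5% and 0.0328%. A simulated list shift was found in 4 of 4 contrasts, with 0 of 351 other tests called. Simulated genes were independent, so false calls of lists of correlated genes and differences among M-on arrays were not tested.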

Results

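Liver RNA was measured on 15 Affymetrix mouse arrays, with 3 biological replicates in each of 5 groups of mice labelled as adult males, of which the arrays labelled M-on 1 and 2 gave female-type sex-linked signals, described below. Transgenic mice carried human alpha1-antitrypsin under a switch that acts in hepatocytes and that doxycycline shuts off. Alpha1-antitrypsin is a protease inhibitor that the liver secretes into blood. Its Z variant misfolds and is retained in the endoplasmic reticulum (ER), whereas M is the common wild type form. Z-on and M-on mice drank no doxycycline and so expressed the transgene by design. Z-off and M-off mice received doxycycline at 40 µg per mL of drinking water from conception, and nontransgenic littermates without doxycycline made up the remaining group. No probe set for the human transgene is used here, so the arrays did not check its expression. Mouse Serpina1b and Serpina1c, the mouse relatives of the transgene, did not rise in either line when it was on, except that Serpina1b passed in M-on minus M-off after quantile normalization (log2 change 0.33, adjusted p = 0.0214). Of probe sets shared by several Serpina1 genes, that of Serpina1b, Serpina1c and Serpina1e was lower in the on groups of both lines (log2 change -1.51 in the Z line, adjusted p = 1.04e-04 and 5.40e-05). That of Serpina1a and Serpina1d was also lower in both (log2 change -0.95 and -0.92, adjusted p = 2.38e-04 and 1.65e-04).

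The deposited values were linear signals for 22690 probe sets, of which 12393 genes entered the tests with 1 probe set each. The number of arrays limited the precision. The first principal component held 49.5% of the variance and ordered the groups from M-off (-41.9 ± 1.49, SD, n = 3) and Z-off (-37.7 ± 2.63) through littermates (4.65 ± 3.68) to Z-on (29.5 ± 4.56) and M-on (45.5 ± 3.66). Control probe sets also separated the on arrays from the others. Poly-A controls, bacterial RNAs added to a sample before labelling, had a median signal of 2.43 ± 0.506 on Z-on and 4.50 ± 0.964 on M-on arrays, against 57.2 ± 4.39 on Z-off, 60.8 ± 8.81 on M-off and 45.7 ± 4.51 on littermate arrays. The 5' probe set of 18S ribosomal RNA read 2354 ± 418 and 2239.7 ± 426 on Z-on and M-on arrays, 369 ± 201 and 273 ± 150.2 on Z-off and M-off arrays, and 196 ± 109 on littermate arrays. The median signal of an array was 50.0 ± 2.37 in Z-on, 48.6 ± 5.69 in M-on, 32.1 ± 0.115 in Z-off, 30.7 ± 0.52 in M-off and 43.5 ± 1.33 in littermates. Median signals of hybridization control probe sets averaged 250, 263, 535, 544 and 510 in Z-on, M-on, Z-off, M-off and littermates. In the same order the ratio of 3' to 5' signal was 1.57, 1.44, 1.89, 1.79 and 2.41 for actin. For Gapdh it was 0.940, 0.872, 0.820, 0.780 and 1.09. The comparisons of on with off arrays and of any transgenic group with littermates therefore ran across arrays that also differed in these controls. Z-off and M-off arrays overlapped in the poly-A and 18S signals, but not in the Gapdh ratio, at 0.817 to 0.824 and 0.755 to 0.806. Z-on and M-on arrays overlapped in the 18S signal, but their low poly-A signals lay apart, at 1.85 to 2.75 and 3.8 to 5.6. Correlations between arrays of a group were lowest in M-on, at 0.943 to 0.969, and 0.968 to 0.986 in the other groups. M-on 1 had higher correlations with the 3 Z-on arrays (0.964 to 0.965) than with M-on 2 and 3 (0.956 and 0.943), and M-on 2 and 3 lay apart on the second component, at 34.9 and 35.6 against at most 8.17 on the other 13 arrays. Comparisons with M-on therefore depended on which of its arrays were kept. Where a signal lay near or below the added constant of 16, the size of a log2 change depended on that constant, here and below.

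**Figure D1:**
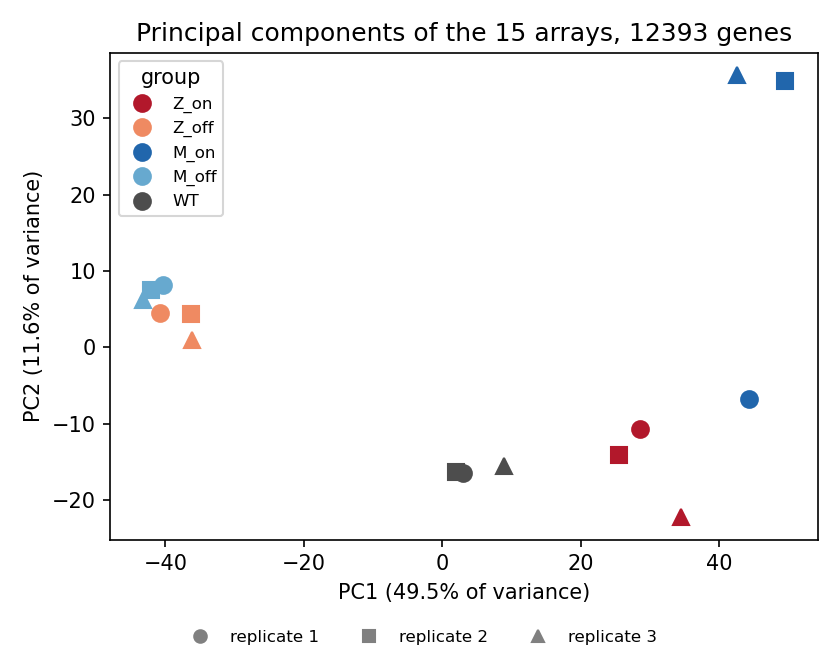
Scores of the 15 arrays on the first (49.5% of the variance) and the second principal component (11.6%) of log2 signals, with colour for the group and marker shape for the replicate. Off arrays lie at the left, littermates near 0 and on arrays at the right.

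**Figure D2:**
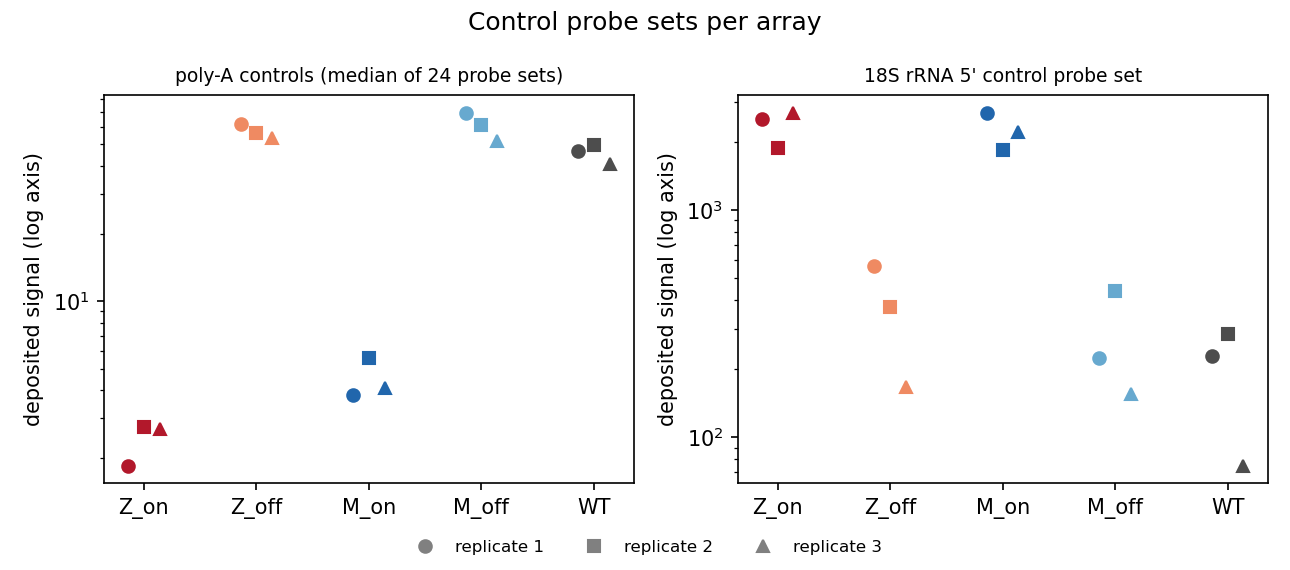
Median signal of the 24 poly-A control probe sets and signal of the 18S 5' control on each array, by group, on a logarithmic axis in linear signal units, with 1 point per array. On arrays have a low poly-A signal and a high 18S signal, and the littermate arrays have neither.

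Rgs16, a regulator of G protein signalling and the gene that the study's publication singled out, was followed in every contrast. Its signal was 277 ± 38.0 (SD, n = 3) in Z-on, 12.8 ± 17.2 in Z-off, 30.4 ± 28.4 in M-on, 2.93 ± 2.00 in M-off and 68.9 ± 40.7 in littermates. The log2 change was 3.50 in Z-on minus Z-off (SE 0.43, adjusted p = 6.21e-05), 2.82 in Z-on minus M-on (SE 0.43, adjusted p = 0.00556) and 1.89 in Z-on minus littermates (SE 0.43, adjusted p = 0.0130). Rgs16 also rose in M-on over M-off, by 1.13 (SE 0.43, adjusted p = 0.0433), a call that ended after quantile normalization (adjusted p = 0.157) and without array M-on 2 (log2 change 0.66). The difference between the on-off changes of the Z and M lines was 2.37 and did not pass (adjusted p = 0.0988), but it did without arrays M-on 1 and 2 (3.05, adjusted p = 0.0141). Its other 2 probe sets changed by 3.41 and 2.57 in Z-on minus Z-off and did not pass against littermates (adjusted p = 0.0529 and 0.316). Rgs16 lay below littermates in both off groups, with log2 changes of -1.61 in Z-off (adjusted p = 0.0164) and -2.06 in M-off (adjusted p = 0.00406). A constant of 1 in place of 16 before the logarithm ended the calls against M-on and against littermates, and a fit of only Z-on and M-on ended the former too (adjusted p = 0.0792). Because it is known from the publication, Rgs16 is not independent evidence here.

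The unfolded protein response raises folding capacity in the ER. None of its 4 genes followed in every contrast was called higher in Z-on than in Z-off before quantile normalization. Hspa5, the main ER chaperone, read 3067 ± 1006 in Z-on and 3941 ± 649 in Z-off (log2 change -0.39, SE 0.29, adjusted p = 0.295, n = 3), and its second probe set fell by 0.87 (adjusted p = 0.0134). Dnajb9 went from 981 ± 358 in Z-off to 1507 ± 420 in Z-on (log2 change 0.64, adjusted p = 0.0950), and passed after quantile normalization (adjusted p = 0.0451). Xbp1 (adjusted p = 0.978) and the pro-apoptotic factor Ddit3 (adjusted p = 0.865) did not pass in Z-on minus Z-off. In M-on, Hspa5 fell by 1.24 (SE 0.29, adjusted p = 0.00263), Dnajb9 fell by 1.23 (SE 0.29, adjusted p = 0.00300) and Ddit3 fell by 0.91 (SE 0.17, adjusted p = 7.16e-04) on the log2 scale from their M-off levels, whereas Xbp1 did not pass (adjusted p = 0.460). Of the other 3 Xbp1 probe sets, 2 rose in M-on minus M-off, by 0.54 and 0.49 (adjusted p = 0.0130 and 0.0281), and the third fell by 0.44 in Z-on minus Z-off (adjusted p = 0.0394). The Z-on minus Z-off change exceeded that of the M line by 0.85 for Hspa5, 1.87 for Dnajb9 and 0.86 for Ddit3, none past the threshold (adjusted p = 0.341, 0.0570 and 0.125). Against littermates Dnajb9 was higher in M-off (log2 change 0.85, adjusted p = 0.0437) and not called in M-on (-0.38, adjusted p = 0.370). Hspa5 was lower than littermates in M-on (-0.92, adjusted p = 0.0322) and not called in M-off (0.33, adjusted p = 0.433). Ddit3 passed in neither (adjusted p = 0.0552 in M-on and 0.0877 in M-off). Serpina1b and Serpina1c were below littermates in every transgenic group. Serpina1c was 8314 ± 268 in Z-on and 16957.8 ± 2744 in littermates (log2 change -1.02, SE 0.13, adjusted p = 6.19e-04), and these falls were lost or turned to small rises after quantile normalization.

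**Figure D3:**
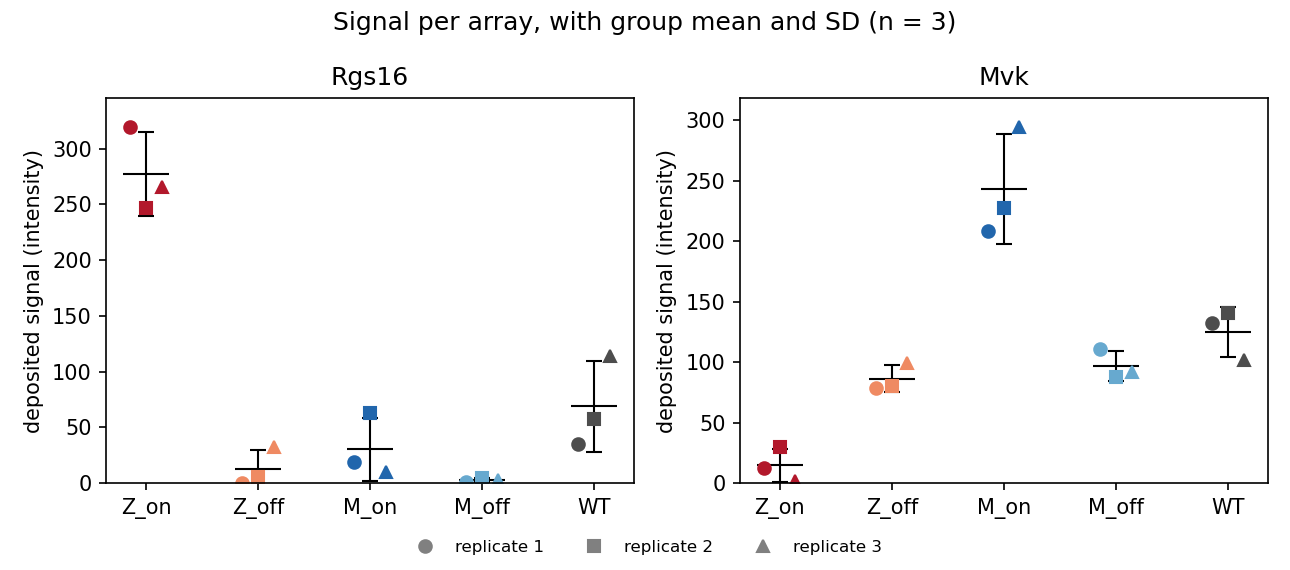
Signal of Rgs16 and Mvk on each of the 15 arrays (points) with the mean and SD of the 3 arrays per group (bars), in linear signal units. Rgs16 is highest in Z-on and Mvk is lowest in Z-on and highest in M-on.

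Turning on the Z protein was compared with keeping it off in Z-on minus Z-off. Usp2, a clock-controlled protease, rose from 37.3 ± 33.9 in Z-off to 397 ± 152 in Z-on (log2 change 3.11, SE 0.43, adjusted p = 1.14e-04, n = 3). Noct, a rhythmic regulator of metabolism, rose from 43.9 ± 28.3 to 484 ± 172 (log2 change 3.14, SE 0.64, adjusted p = 0.00168). Lpin1, which acts in triglyceride synthesis and in fasting, rose by 2.91 (SE 0.39, adjusted p = 9.99e-05). Cyp51, an enzyme of cholesterol synthesis, fell from 512 ± 64.8 to 90.8 ± 26.8 (log2 change -2.33, SE 0.21, adjusted p = 1.11e-05), and Idi1 of the same route fell by 2.36 (SE 0.41, adjusted p = 5.55e-04).

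The other large rises after Rgs16 were those of Gstp3, Cyp2c37, Fbxo36, Cysrt1, Cdsn, Il20, Casr and Arid5a, with log2 changes of 2.35 to 3.13. The other large falls were those of AY036118, Dnase2a, Ggact, Egr1, Pfn1, Csad, Sp3, Rbbp9, Clec2d and Elovl3, with log2 changes of -2.16 to -3.33. All 3 arrays of one group lay beyond all 3 of the other for each of these genes, by the rule that chose them. Of these 24 genes, 20 passed with any single array left out. The calls of Gstp3, Cyp2c37, Egr1 and Elovl3 each ended without 1 of several arrays.

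Cholesterol synthesis and uptake had the median furthest from that of all genes among the 40 lists in Z-on minus Z-off. Of its 22 measured genes, 14 fell, 3 rose and 5 did not pass, with the same 14 falls and 3 rises when adjusted over the list alone. Tm7sf2 fell by 1.56, Pmvk fell by 1.56 and Fdft1 fell by 1.55, beside Cyp51. The list's median was -1.62 relative to all genes (adjusted p = 1.63e-08, and adjusted p = 0.469 with an estimated correlation). Targets of NRF2, which answer oxidative stress, gave 10 falls, among them Sod1, Cat and Osgin1 with log2 changes of -0.70 to -1.84, and 2 rises, of which Slc7a11 rose by 0.95, among 34 genes (2 higher and 10 lower adjusted over the list alone). That list's test gave adjusted p = 5.89e-07, and adjusted p = 0.381 with an estimated correlation. Cytosolic ribosomal proteins fell in 16 of 33 genes, such as Rps29, Rps19, Rps20 and Rps14 (16 adjusted over the list alone, adjusted p = 1.27e-09, and adjusted p = 0.571 with an estimated correlation), and after quantile normalization 10 fell and 2 rose. Of 59 nuclear-encoded respiratory chain genes 25 fell, such as Ndufa4, Atp5e, Atp5h and Atp5pb, and 3 rose (25 and 3 adjusted over the list alone, adjusted p = 8.01e-12, and adjusted p = 0.621 with an estimated correlation). Quantile normalization ended the respiratory chain call (adjusted p = 0.195).

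Circadian clock and output genes had 14 rises and 3 falls among 28 genes, or 17 and 6 adjusted over the list alone, and the list was not called (adjusted p = 0.202, and adjusted p = 0.781 with an estimated correlation) until after quantile normalization (adjusted p = 0.0233). Hlf, a transcription factor of clock output, rose from 125 ± 6.25 to 279 ± 26.3 (log2 change 1.06, SE 0.14, adjusted p = 1.03e-04, n = 3). ER chaperones and folding enzymes gave 7 falls, Canx, Pdia3 and Pdia4 among them, and 2 rises, of which Herpud1, a component of ER-associated degradation, rose by 1.09 (SE 0.21, adjusted p = 0.00109). Their list of 36 had 7 falls adjusted over the list alone and a median of -0.24 relative to all genes (adjusted p = 0.00729, and adjusted p = 0.781 with an estimated correlation). That call was lost after quantile normalization (adjusted p = 0.873) and without array Z-on 1 (adjusted p = 0.0517). Proteasome subunits fell in 7 of 36 genes, among them Psma1, Psmb2, Psmc1 and Psma5, and rose in 2 (7 and 1 adjusted over the list alone, adjusted p = 1.27e-06, and adjusted p = 0.621 with an estimated correlation). Quantile normalization ended that call too (adjusted p = 0.0851).

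In all, 3913 genes were higher and 925 lower in Z-on than in Z-off by limma (4838 of 12393), and 1437 and 201 of them by more than 1 log2 unit. The median log2 change of all genes was 0.25, and 0 of the genes called higher lay below that median. After quantile normalization 1934 genes were higher and 1277 lower, 60.2% against 80.9% higher. Of the 40 lists 11 were called, the others being acute phase proteins, exocrine pancreas and adipose, hepatocyte secretory, male-type liver and mitochondrial ribosome genes, all lower. Of these 5 calls, quantile normalization ended all but that of pancreas and adipose (adjusted p = 0.291 to 0.812) and turned the hepatocyte secretory median to 0.07. The pancreas and adipose call ended without array Z-off 1 (adjusted p = 0.226), and it and the acute phase call ended without dim genes (adjusted p = 0.130 and 0.0527). Kupffer cell genes were called lower only after quantile normalization (adjusted p = 0.0258). List medians here and below are given relative to the median of all genes, and no list passed in any contrast with an estimated correlation.

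Turning on the wild type M protein was compared with keeping it off in M-on minus M-off, where genes that differ between male and female liver were among the largest changes. Cyp2b9, a cytochrome P450 typical of female liver, rose from 12.7 ± 3.00 in M-off to 1495 ± 1292 in M-on (log2 change 4.41, SE 1.03, adjusted p = 0.00294, n = 3). Xist, the transcript that silences an X chromosome in female cells, rose from 15.6 ± 2.25 to 469 ± 597 (log2 change 2.92, SE 0.73, adjusted p = 0.00458), and Eif2s3y, a Y-linked gene, fell from 349 ± 77.0 to 14.6 ± 23.8 (log2 change -3.82, SE 0.38, adjusted p = 6.07e-06). The Xist signal was 1149.2 on the array labelled M-on 1, 226.0 on M-on 2 and 32.6 on M-on 3, against at most 74.3 on the other 12 arrays. Eif2s3y read 0.4, 1.3 and 42.1 on the same 3 arrays, against at least 105.3 on the other 12. Of 3 Kdm5d and 2 Uty probe sets, also Y-linked, 1 of each likewise read lower on all 3 M-on arrays than on the other 12, at 12, 11.4 and 23.2 against at least 43.6 for Kdm5d, and 4.6, 5.6 and 8.5 against at least 22.8 for Uty. Without the arrays labelled M-on 1 and 2, the changes of Sult2a2, Cyp2b9, Cyp2b13, Acot3 and Xist were 0.53 to 0.75 and did not pass, so these genes describe those arrays more than the M-on group. Genes of female liver rose in 17 of 25 and fell in 1 (19 and 1 adjusted over the list alone), and the list was not called (adjusted p = 0.0839, and adjusted p = 0.839 with an estimated correlation) until after quantile normalization (adjusted p = 0.0120).

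**Figure D4:**
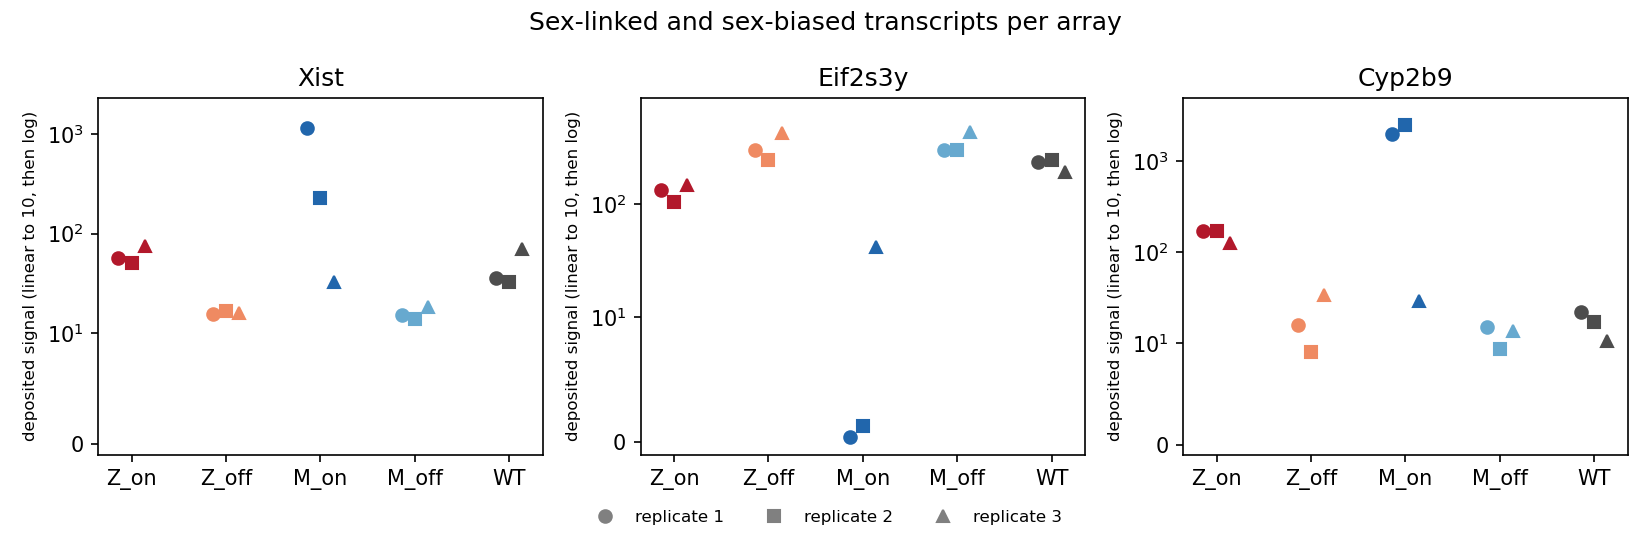
Signal of Xist, Eif2s3y and Cyp2b9 on each of the 15 arrays, by group, with 1 point per array, on an axis in signal units that is linear up to 10 and logarithmic above. The arrays labelled M-on 1 and 2 carry the highest Xist and Cyp2b9 signals and the lowest Eif2s3y signals.

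Cyp2c39, an arachidonic acid epoxygenase, had the largest rise, from 5.13 ± 5.91 to 1404 ± 1048 (log2 change 5.77, SE 0.77, adjusted p = 5.13e-05). Its M-off signal was near the background, and the change was 7.95 with 1 and 4.11 with 64 in place of 16. The other large rises in M-on were those of Sult2a2, Cyp2b13, Nnmt, Rdh16f2, Cyp2c38, Acot3, Oxt, Slc22a26 and Pctp, with log2 changes of 2.89 to 5.19. Apob, the carrier protein of lipoproteins, fell from 6201 ± 697 to 892 ± 634 (log2 change -2.98, SE 0.36, adjusted p = 2.56e-05). The other large falls were those of Clec2d, Prpf4b, Sdf2l1, Sp3, Cpeb4, Malat1, Tmed5, Cyp2c55, Ubxn2a and Lrrc58, with log2 changes of -2.75 to -3.31. All 24 passed with any single array left out, and Malat1 did not pass without arrays M-on 2 and 3 (log2 change -0.70).

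ER chaperones fell in 14 of 36 genes in M-on and none rose, with the same 14 adjusted over the list alone. Pdia3, a disulphide isomerase, fell from 2444 ± 40.8 to 816 ± 148 (log2 change -1.58, SE 0.16, adjusted p = 6.07e-06), and Hsp90b1, Pdia4 and Canx fell by 1.69, 1.41 and 1.07. The list's median was -0.62 (adjusted p = 9.61e-08, and adjusted p = 0.621 with an estimated correlation). Cytosolic heat shock genes fell in 13 of 23 and rose in 1 (14 and 2 adjusted over the list alone, adjusted p = 2.89e-06, and adjusted p = 0.621 with an estimated correlation). Among them Hspa1b, an inducible Hsp70, fell by 2.66 (SE 0.53, adjusted p = 0.00105), with Dnaja1, Dnajb4 and Hsp90aa1 at log2 changes of -1.17 to -1.75. Genes more abundant in male liver fell in 15 of 27 and rose in 2 (16 and 2 adjusted over the list alone, adjusted p = 4.55e-06, and adjusted p = 0.621 with an estimated correlation). The male-type list was not called without arrays M-on 1 and 2 (adjusted p = 0.259). Of these, Mup3, Ugt2b1 and Gstp1 fell by 1.93, 1.22 and 1.20, and Scnn1a rose by 1.11.

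Ribosomal proteins fell in 14 of 33 genes, such as Rps29, Rps20, Rpl22 and Rps19, and rose in 1 (14 and 1 adjusted over the list alone, adjusted p = 9.79e-08, and adjusted p = 0.621 with an estimated correlation). Respiratory chain genes fell in 18 of 59, such as Ndufa4, Ndufa5, Cycs and Ndufa6, and rose in 6 (17 and 6 adjusted over the list alone, adjusted p = 9.56e-07, and adjusted p = 0.733 with an estimated correlation). Quantile normalization ended that call (adjusted p = 0.332), as did leaving out arrays M-on 1 and 2 (adjusted p = 0.0606). Circadian genes rose in 10 and fell in 3 of 28 (10 and 3 adjusted over the list alone), with the list not called (adjusted p = 0.682, and adjusted p = 0.927 with an estimated correlation). Wee1, Tef and Nr1d1 rose by 1.77, 1.37 and 1.73, and Clock fell by 2.12. By limma, 4702 genes were higher and 1537 lower in M-on than in M-off (6239 of 12393), 1991 and 594 of them by more than 1 log2 unit, with a median of all genes of 0.29 and 12 called-higher genes below it. After quantile normalization 2900 were higher and 1901 lower, 60.4% against 75.4% higher. Of the lists 8 were called, the others being hepatocyte secretory genes, NRF2 targets and mitochondrial ribosome genes, all lower. Quantile normalization ended these 3 calls (adjusted p = 0.592 to 0.973) and turned the hepatocyte secretory median to 0.01. The NRF2 and mitochondrial ribosome calls also ended without array M-on 1 (adjusted p = 0.246 and 0.328) and without dim genes (adjusted p = 0.130 for both), and that of NRF2 without M-on 2 or M-off 3 (adjusted p = 0.0589 and 0.0719). Fatty acid oxidation was called higher only after quantile normalization (adjusted p = 0.00788), and bile acid genes lower only without M-on 1 and 2 (adjusted p = 0.0239).

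Whether the on-off change differed between the Z and M lines was tested as the difference of both changes, in which a shift common to both on groups cancels. Mvk, mevalonate kinase of cholesterol synthesis, went from 86.2 ± 11.2 to 14.8 ± 13.9 in the Z line and from 96.9 ± 12.3 to 243 ± 45.4 in the M line (difference -3.02, SE 0.37, adjusted p = 0.00623, n = 3 per group). Cyp51 differed by -2.47 (SE 0.30, adjusted p = 0.00623), Fdft1 by -1.77 (SE 0.27, adjusted p = 0.0197) and Sqle by -2.77 (SE 0.42, adjusted p = 0.0199), and these 3 enzymes were each low in Z-on alone. The heat shock gene Hspa1b went from 282 ± 86.5 to 617 ± 348 in the Z line and from 1369 ± 332 to 246 ± 172 in the M line (difference 3.66, SE 0.76, adjusted p = 0.0454). Nox4, an oxidase that makes hydrogen peroxide, differed by 2.72 (SE 0.40, adjusted p = 0.0197), with Gna14 and Susd4 at 2.77 and 2.74. Cyp2c39, Cyp2c38 and the lipoprotein receptor gene Vldlr differed by -6.20, -3.53 and -3.48, of which that of Cyp2c39 was -8.46 with a constant of 1 and -4.41 with 64. The Mvk signal in Z-on was at the lower quartile of those arrays, and its difference was -4.31 with a constant of 1, no longer called (adjusted p = 0.0786), and -1.87 with 64. Of the 8 genes with the largest differences, only Mvk passed with any single array left out, and only Nox4, Cyp2c39 and Vldlr with a constant of 1, which ended 10 of the 16 calls of named genes.

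Cholesterol synthesis genes had 7 negative differences and 0 positive among 22, or 16 and 1 adjusted over the list alone, with a median of -1.21 (adjusted p = 4.14e-11, and adjusted p = 0.381 with an estimated correlation). Cytosolic heat shock genes had 4 positive differences and 0 negative among 23 (9 and 0 adjusted over the list alone, adjusted p = 3.67e-08, and adjusted p = 0.573 with an estimated correlation). Dnajb4, Dnaja1 and Chordc1 were at 2.04, 1.26 and 2.13. In the ER chaperone list Herpud1 alone passed, at 1.44 (6 positive and 0 negative of 36 adjusted over the list alone, adjusted p = 1.22e-05, and adjusted p = 0.728 with an estimated correlation). The ER chaperone list was not called without arrays M-on 1 and 2 (adjusted p = 0.129). Circadian genes gave 1 positive difference of 28, that of Per2 at 2.08, or 5 adjusted over the list alone (adjusted p = 6.83e-04, and adjusted p = 0.621 with an estimated correlation). Kupffer cell and macrophage genes gave 0 of 35 over all genes and 4 negative adjusted over the list alone (adjusted p = 4.85e-06, and adjusted p = 0.621 with an estimated correlation). Csf1r, the macrophage growth factor receptor, was at -1.22 (adjusted p = 0.0710) and Slc11a1 at -0.79 (adjusted p = 0.0858). By limma, 38 differences were positive and 38 negative (76 of 12393, with 1887 at an unadjusted p under 0.05), a balance that did not hold under the alternatives given below. Of the lists 12 were called, the others with negative medians for proteasome, pancreas and adipose, fatty acid oxidation, NRF2, MHC class II and female-type liver genes, and a positive median for male-type liver genes. Without arrays M-on 1 and 2 the male-type median turned to -0.38, and without M-on 2 and 3 the proteasome median turned to 0.04, neither called (adjusted p = 0.135 and 0.879). The female-type list was not called without M-on 1 and 2 either (adjusted p = 0.982).

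Single arrays decided several list calls of the interaction, with adjusted p = 0.0507 to 0.210 without them. These were proteasome (Z-on 3 or M-on 3), male-type (M-on 1 or 2), pancreas and adipose (Z-off 1 or M-on 1), fatty acid oxidation (Z-on 2 or M-on 2), NRF2 (M-off 1 or M-on 3) and MHC class II (M-off 1, Z-off 1, Z-on 1 or M-on 1). Quantile normalization ended the calls of fatty acid oxidation and NRF2 (adjusted p = 0.0556 and 0.0809). Leaving out dim genes ended that of pancreas and adipose (adjusted p = 0.421). The pancreas and adipose, fatty acid oxidation and MHC class II lists were not called without M-on 1 and 2 either. Without M-on 1 and 2 the respiratory chain list was called, with a negative direction (adjusted p = 2.02e-04). The count of genes was 1030 without array M-on 1 (786 positive and 244 negative), 1157 with array weights (755 and 402) and 811 without M-on 1 and 2 (665 and 146), and it was 2 to 23 without any 1 of M-off 1, 2 and 3, Z-off 1 and 2, Z-on 1, 2 and 3, M-on 2 and littermates 2 and 3.

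Mutant and wild type protein, both without doxycycline, were compared in Z-on minus M-on. There cholesterol synthesis had the smallest p among the 40 lists. Sqle, the squalene epoxidase, was 81.9 ± 26.8 in Z-on and 915 ± 94.7 in M-on (log2 change -3.28, SE 0.30, adjusted p = 7.53e-05, n = 3). Mvk was 14.8 ± 13.9 against 243 ± 45.4 (log2 change -3.16, SE 0.26, adjusted p = 4.91e-05), Fdps was lower by a log2 change of -2.88 (SE 0.31, adjusted p = 3.23e-04), and Cyp51 by -2.48 (SE 0.21, adjusted p = 5.57e-05). Msmo1, Fdft1, Rdh11 and Mvd changed by -2.11 to -2.07. Of the 22 genes of the list 15 were lower and 0 higher (18 and 1 adjusted over the list alone), with a median of -1.35 (adjusted p = 6.96e-18, and adjusted p = 0.381 with an estimated correlation). The change of Mvk was -4.48 with a constant of 1 and -1.97 with 64, called with both. Against each M-on array alone the list's median was -1.72, -1.08 and -1.31.

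**Figure D5:**
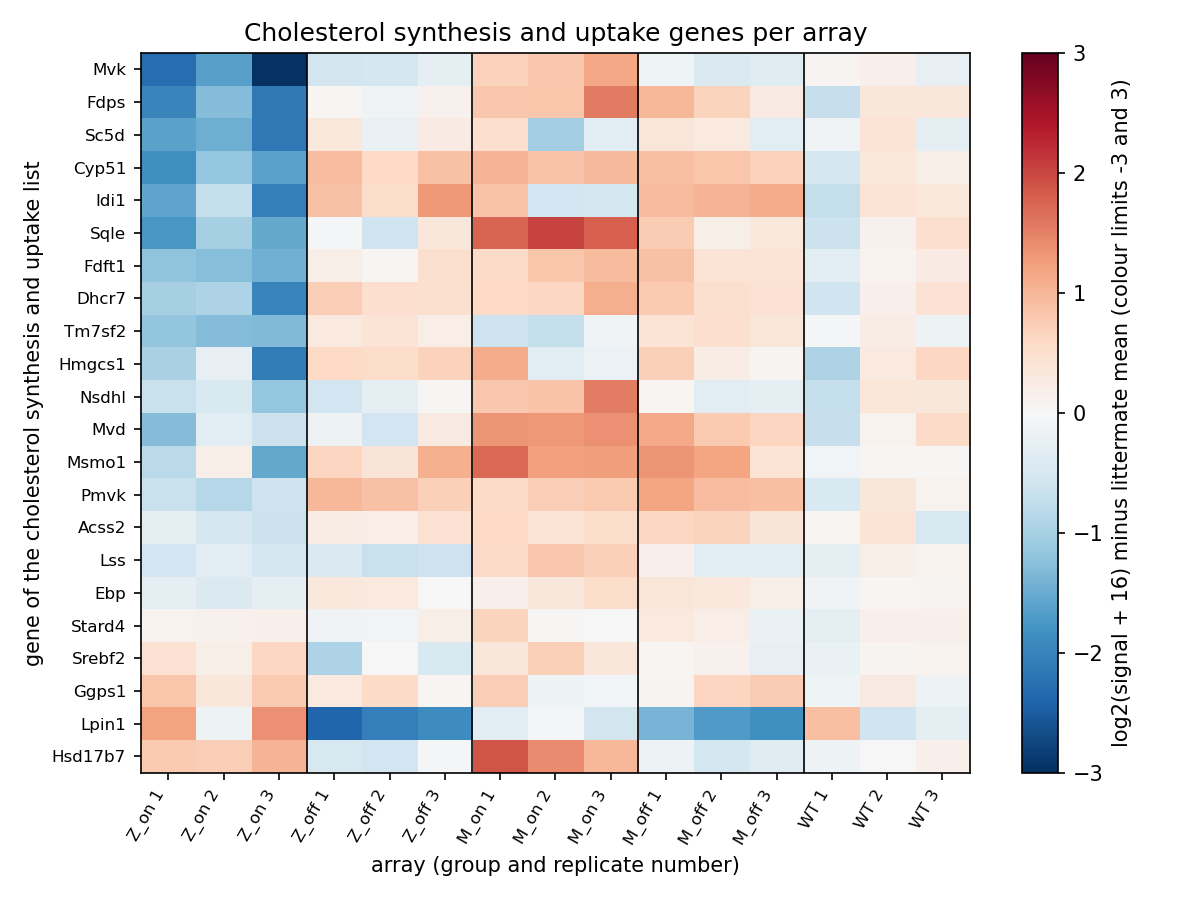
Heat map of 22 cholesterol synthesis and uptake genes (vertical axis) on the 15 arrays (horizontal axis), as log2(signal + 16) minus the littermate mean, with colour limits at -3 and 3. Of the 22 genes, 11 have their 3 lowest values on the 3 Z-on arrays.

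Among genes higher in Z-on than in M-on, Slco1a1, an anion transporter of male-type liver, was 1697 ± 337 against 316 ± 245 (log2 change 2.87, SE 0.57, adjusted p = 0.0180), followed by Rgs16. Nox4 was 272 ± 81.3 against 41.1 ± 3.76 (log2 change 2.30, SE 0.28, adjusted p = 0.00131), and Sema3e, an axon guidance protein, was 78.9 ± 11.3 against 3.53 ± 5.51 (log2 change 2.31, SE 0.34, adjusted p = 0.00421). Eif2s3y was 129 ± 21.7 against 14.6 ± 23.8 (adjusted p = 0.00484). The Sema3e signal in M-on was below the lower quartile of those arrays, and its change was 4.87 with a constant of 1, no longer called (adjusted p = 0.0548), and smaller but called with 64 (adjusted p = 0.00152). Lrrc58, Tlcd4, Ube3a, Bpnt2, Fam126b, Hspa1a and Atp13a3 were higher by 2.21 to 2.52. None of the 7 was called without arrays M-on 2 and 3, where the difference was 0.47 to 0.75 for all but Hspa1a (2.72). The remaining large falls were those of Cyp2c39, Cyp2c38, Snrnp25 and Apcs, a plasma pentraxin, with log2 changes of -2.44 to -2.88. Of the 24 genes with the largest changes 14 passed with any single array left out. The calls of Slco1a1, Lrrc58, Tlcd4, Ube3a, Bpnt2, Fam126b, Hspa1a, Atp13a3, Cyp2c39 and Snrnp25 ended without at least 1 array.

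Kupffer cell and macrophage genes were lower in Z-on than in M-on in 5 of 35 and higher in 0, or 17 and 0 adjusted over the list alone (adjusted p = 5.78e-07, and adjusted p = 0.621 with an estimated correlation). Among them C1qa, a complement component made by macrophages, was 122 ± 12.1 against 346 ± 55.7 (log2 change -1.39, SE 0.24, adjusted p = 0.00951), and Csf1r, C1qc and Cd5l changed by -0.97 to -1.32. Antigen presentation genes of MHC class II were lower in 5 of 12 (8 adjusted over the list alone, adjusted p = 1.34e-04, and adjusted p = 0.621 with an estimated correlation). H2-Ab1, H2-Aa, H2-DMa and Ifi30 were at -0.61 to -1.81. Circadian genes were higher in 2 of 28 (3 adjusted over the list alone, adjusted p = 0.00763, and adjusted p = 0.621 with an estimated correlation), Rgs16 and Hlf. Hlf was higher by 0.83 (SE 0.14, adjusted p = 0.0106), and the list call was lost without array Z-on 3 (adjusted p = 0.0589) and without M-on 2 and 3 (adjusted p = 0.103). Bile acid and sterol metabolism genes were higher in 4 of 28 (4 adjusted over the list alone, adjusted p = 0.0241, and adjusted p = 0.733 with an estimated correlation). Beside Slco1a1, the transporters Slco1b2, Abcc2 and Abca1 were at 1.04 to 1.71. The bile acid call ended without array Z-on 1 (adjusted p = 0.107) or M-on 3 (adjusted p = 0.0941), without M-on 2 and 3 (adjusted p = 0.743) and without dim genes (adjusted p = 0.0762).

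Genes of female liver were lower in Z-on than in M-on in 3 of 25, Cyp3a16, Cyp3a44 and Cux2 (9 adjusted over the list alone, adjusted p = 1.87e-04, and adjusted p = 0.757 with an estimated correlation). Genes of male liver were higher in 2 of 27, Slco1a1 and Ugt2b1 (6 higher and 1 lower adjusted over the list alone, adjusted p = 0.0216, and adjusted p = 0.781 with an estimated correlation). Both medians changed sign without arrays M-on 1 and 2, and the male-type list was then called lower (adjusted p = 0.00473). The female-type call also ended without M-on 1 alone (adjusted p = 0.0675), and the male-type call without M-on 1 or M-on 2 alone (adjusted p = 0.433 and 0.243) or without dim genes (adjusted p = 0.0678). In the proteasome list Psmb10 fell by 0.82, the only one of 36 to pass (6 lower and 1 higher adjusted over the list alone, adjusted p = 0.00224, and adjusted p = 0.757 with an estimated correlation). The proteasome median changed sign without arrays M-on 2 and 3, and the call ended without Z-on 3 or M-on 3 alone (adjusted p = 0.0685 and 0.205). ER-associated degradation genes Edem3 and Ngly1 were higher by 1.75 and 0.64, without a call for their list of 30 (3 higher and 1 lower adjusted over the list alone, adjusted p = 0.371, and adjusted p = 0.881 with an estimated correlation). By limma, 453 genes were higher and 186 lower (639 of 12393, with 2452 at an unadjusted p under 0.05), 256 and 62 of them by more than 1 log2 unit. Of the lists 12 were called, the others being acute phase, liver endothelial, fatty acid oxidation and ribosomal protein genes, all lower.

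These 4 calls each ended under some alternative. Quantile normalization ended those of acute phase, fatty acid oxidation and ribosomal protein genes (adjusted p = 0.0882 to 0.504). Single arrays ended those of acute phase (Z-on 1 or M-on 1), endothelial (M-on 2), fatty acid oxidation (Z-on 2 or M-on 2) and ribosomal protein genes (Z-on 2 or M-on 3), with adjusted p = 0.0551 to 0.504. Without both M-on 1 and 2 the acute phase, endothelial and fatty acid oxidation lists were not called (adjusted p = 0.149 to 0.369), and the NRF2, respiratory chain and mitochondrial ribosome lists were called lower (adjusted p = 6.80e-05 to 0.0103). Each array of both groups decided the count of genes, which was 227, 159 and 109 without Z-on 1, 2 and 3, and 1677, 76 and 214 without M-on 1, 2 and 3. Without both M-on 1 and 2 the count was 1272, of which 485 were among the 639. It was 18 with only these groups in the fit, which ended 16 of the 24 named calls. A constant of 1 ended 25 of the 43 calls of named genes. The excess of higher genes was lost without M-on 2 (36 higher and 40 lower), without M-on 3 (106 and 108), without both (26 and 43) and with only these groups in the fit (6 and 12).

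Z-on mice were compared with littermates, across arrays that differed in poly-A and 18S signals. Cyp2c37, a cytochrome P450 of arachidonic acid metabolism, was 2282 ± 615 in Z-on and 26.8 ± 12.9 in littermates (log2 change 5.76, SE 1.10, adjusted p = 0.00483, n = 3), and it was also raised in M-off. Abcc2, which exports conjugates into bile, rose by 2.05 (SE 0.25, adjusted p = 5.31e-04), and Cyp26a1, which degrades retinoic acid, by 1.96 (SE 0.39, adjusted p = 0.00567). Pfn1, an actin-binding protein, fell from 1769 ± 122 to 232 ± 95.4 (log2 change -2.94, SE 0.24, adjusted p = 4.91e-05), and Mvk fell by 2.28 (SE 0.26, adjusted p = 3.26e-04). Evi5, Fbxo36, Serpinb1a, Sema3e, Rgs16, Srf, Cysrt1, Cdk5rap1 and Crim1 rose by 1.74 to 2.16. The falls of AY036118, Ggact, Apcs, Snrnp25, Sdf2l1, Saa2, Arhgap9, Mndal, Fdps and Hc had log2 changes of -1.79 to -3.39. Of these 24 genes 20 passed with any single array left out, all but Rgs16 (adjusted p = 0.0512 without littermate 1), Snrnp25, Mndal and Hc.

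Kupffer cell genes were lower in Z-on than in littermates in 8 of 35 and higher in 0 (10 and 1 adjusted over the list alone, adjusted p = 7.22e-05, and adjusted p = 0.621 with an estimated correlation). Csf1r was 348 ± 71.4 against 885 ± 218 (log2 change -1.30, SE 0.20, adjusted p = 0.00144), with C1qc, C1qb and C1qa at -0.90 to -1.37. MHC class II genes were lower in 6 of 12 (6 adjusted over the list alone, adjusted p = 0.00364, and adjusted p = 0.621 with an estimated correlation). H2-DMa, Cd74, H2-Ab1 and H2-Aa were at -0.99 to -1.68. Fibrosis and stellate cell genes rose in 8 of 40 (10 adjusted over the list alone, adjusted p = 0.00763, and adjusted p = 0.621 with an estimated correlation). Among them Ccn2, a matrix-associated growth factor, rose from 32.3 ± 17.2 to 135 ± 37.6 (log2 change 1.67, SE 0.28, adjusted p = 0.00233), and Timp2, Mmp14 and Mmp2 by 0.56 to 0.83, with 5 rises in the list after quantile normalization. Cholesterol synthesis genes fell in 10 of 22 and rose in 1 (16 and 2 adjusted over the list alone), with a median of -0.81 (adjusted p = 1.30e-07, and adjusted p = 0.539 with an estimated correlation). Tm7sf2, Cyp51 and Fdft1 were at -1.26 to -1.53.

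ER chaperones fell in 8 of 36 (8 adjusted over the list alone, adjusted p = 1.22e-05, and adjusted p = 0.728 with an estimated correlation). Pdia3, Pdia4 and Canx were at -0.76 to -1.40. Acute phase proteins, which the liver secretes in inflammation, fell in 12 of 30 and rose in 1 (14 and 2 adjusted over the list alone, adjusted p = 1.01e-06, and adjusted p = 0.381 with an estimated correlation). Orm1 fell by 1.13, Itih4 fell by 0.78 and Il1rn rose by 1.34, and the list was not called after quantile normalization (adjusted p = 0.125). Of 32 secretory and identity genes of hepatocytes 19 fell (22 lower and 1 higher adjusted over the list alone, adjusted p = 3.03e-12, and adjusted p = 0.381 with an estimated correlation). Among them Apoa1, Apoc3, Apoa2 and Alb were at -0.88 to -1.03, but quantile normalization turned the list's median to 0.06 and ended these 4 calls. Ribosomal proteins fell in 17 of 33 (23 lower and 1 higher adjusted over the list alone, adjusted p = 9.57e-13, and adjusted p = 0.381 with an estimated correlation). Rps19, Rpl19, Rpl35 and Rps20 were at -0.85 to -0.96. After quantile normalization 5 ribosomal proteins fell and 1 rose, and the list stayed called (adjusted p = 0.00407). By limma, 906 genes were higher and 574 lower (1480 of 12393), 200 and 108 of them by more than 1 log2 unit, and 932 without array Z-on 3. After quantile normalization 559 were higher and 558 lower, 50.0% against 61.2% higher. Of the lists 13 were called, the others being proteasome, male-type liver, respiratory chain, interferon response and alpha1-antitrypsin family genes, all lower. Quantile normalization ended these calls except that of interferon response (adjusted p = 0.242 to 0.998) and turned the median of the alpha1-antitrypsin family to 0.03. Xenobiotic metabolism was called higher only after it (adjusted p = 0.00611). Single arrays ended the proteasome (Z-on 3 or littermate 1, adjusted p = 0.137 and 0.0623), male-type (littermate 1, adjusted p = 0.105) and interferon calls (Z-on 1 or 2, adjusted p = 0.145 and 0.0569).

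M-on mice differed from littermates in Anxa5, a membrane-binding annexin, which rose from 32.0 ± 12.9 to 302 ± 83.4 (log2 change 2.73, SE 0.40, adjusted p = 6.61e-04, n = 3), and in Hc, complement component C5, which fell to 394 ± 315 (log2 change -3.20, SE 0.43, adjusted p = 4.72e-04). Cyp2b9, Cyp2b13 and Gstp3 rose by 3.04 to 4.24, and Slco1a1, Tmed5 and Eif2s3y changed by -3.24 to -3.30. The rises of Cyp2b9 and Cyp2b13 were 0.49 and 0.32 and not called without arrays M-on 1 and 2. Of the 8 genes 6 passed with any single array left out, not Cyp2b13 and Gstp3. Fibrosis and stellate cell genes rose in 14 of 40 (17 adjusted over the list alone, adjusted p = 5.77e-04, and adjusted p = 0.621 with an estimated correlation). Timp2, Mmp14, Bgn and Sparc were at 1.26 to 1.40, and the list was not called without arrays M-on 1 and 2 (adjusted p = 0.129). Cholesterol synthesis genes rose in 11 of 22 and fell in 1 (14 and 1 adjusted over the list alone), with a median of 0.61 (adjusted p = 0.00242, and adjusted p = 0.621 with an estimated correlation). Sqle rose from 255 ± 101 to 915 ± 94.7 (log2 change 1.85, SE 0.30, adjusted p = 0.00111), with Hsd17b7, Cyp51 and Mvd at 0.95 to 1.43.

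Genes of female liver rose in 13 of 25 in M-on (17 higher and 2 lower adjusted over the list alone, adjusted p = 0.00148, and adjusted p = 0.757 with an estimated correlation), such as Slc22a26 and Cyp3a44. Genes of male liver fell in 11 of 27 and rose in 2 (14 and 3 adjusted over the list alone, adjusted p = 3.73e-04, and adjusted p = 0.748 with an estimated correlation), with Gstp1, Mup3 and Cyp2f2 at -0.72 to -2.08. Without arrays M-on 1 and 2 these medians were -0.00391 and 0.24. ER chaperones fell in 11 of 36 (11 adjusted over the list alone, adjusted p = 1.96e-05, and adjusted p = 0.733 with an estimated correlation). Pdia3, Pdia4, Canx and Erp44 were at -0.69 to -1.52. That call was lost without arrays M-on 1 and 2 (adjusted p = 0.0606). By limma, 1789 genes were higher and 1169 lower (2958 of 12393), 344 and 386 of them by more than 1 log2 unit, and 1903 without array M-on 2. Without arrays M-on 1 and 2 the balance turned, to 934 higher and 1120 lower. Of the lists 10 were called, the others being acute phase, hepatocyte secretory, respiratory chain and ribosomal protein genes, lower, and liver endothelial genes, higher. Quantile normalization ended these 5 calls (adjusted p = 0.0730 to 0.990), and fatty acid oxidation was called higher only after it (adjusted p = 0.0420). Without M-on 1 and 2 the acute phase, endothelial and respiratory chain lists were not called (adjusted p = 0.0606 to 0.534), and proteasome genes were called higher and bile acid genes lower (adjusted p = 0.0334 and 0.0446). Single arrays ended those of acute phase (littermate 1), respiratory chain (M-on 1) and endothelial genes (M-on 2 or littermate 3), with adjusted p of at most 0.139.

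With the transgene off, Z-off minus M-off compared the lines on arrays that overlapped in their poly-A and 18S signals. Their Gapdh ratios, given above, did not overlap. Pik3c2g, a lipid kinase of hepatocytes, was 112 ± 10.7 in Z-off and 16.8 ± 2.30 in M-off (log2 change 1.96, SE 0.16, adjusted p = 1.18e-04, n = 3). Vldlr, Hsd17b6 and Cdh1 were higher by 2.07 to 2.66, and Pck1, the fasting-induced enzyme of glucose synthesis, by 1.17 (SE 0.18, adjusted p = 0.0249). Apcs fell by 2.01 (SE 0.32, adjusted p = 0.0333), and Asic5, Corin and Lactb changed by -1.30 to -1.89. Of the 8 genes with the largest changes, only Pik3c2g passed with any single array left out. Cytosolic heat shock genes were lower in Z-off in 0 of 23 over all genes and in 9 adjusted over the list alone, with a median of -0.58 (adjusted p = 3.03e-12, and adjusted p = 0.381 with an estimated correlation). The lowest p were those of Dnajb1 at -1.14 (adjusted p = 0.0963) and Fkbp4 at -0.64 (adjusted p = 0.0992). ER chaperones were lower in 0 of 36 over all genes and 3 adjusted over the list alone (adjusted p = 9.64e-10, and adjusted p = 0.621 with an estimated correlation), with Herpud1 at -0.94 (adjusted p = 0.102). Genes of exocrine pancreas and adipose tissue were higher as a list with 0 of 20 past the threshold, also when adjusted over the list alone (adjusted p = 1.29e-06, and adjusted p = 0.621 with an estimated correlation). The list was led by the pancreatic lipase cofactor Clps at 1.46 (adjusted p = 0.227) and Cela3b at 1.23 (adjusted p = 0.264). By limma, 11 genes were higher and 6 lower (17 of 12393, with 1167 at an unadjusted p under 0.05). Of the lists 9 were called, the others being acute phase, cholesterol synthesis, fatty acid synthesis and ribosomal protein genes, lower, and gluconeogenesis genes and NRF2 targets, higher. Quantile normalization ended those of acute phase and fatty acid synthesis (adjusted p = 0.0784 and 0.0549). Single arrays ended those of acute phase (M-off 2, Z-off 2 or 3), fatty acid synthesis (M-off 1 or 3, Z-off 1 or 2), cholesterol synthesis and NRF2 (M-off 1) and gluconeogenesis (Z-off 1), with adjusted p = 0.0512 to 0.113. The female-type list was called higher only without M-on 1 and 2 (adjusted p = 0.00975). The count of genes was 6 to 11 without any 1 of M-off 1, 2 and 3, Z-off 1 and 2, Z-on 1 and 2 and littermates 2 and 3, and 51, 28 and 40 without Z-off 3, Z-on 3 and littermate 1.

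Both off groups were set against littermates without doxycycline or transgene. Usp2 fell by 3.26 in Z-off (SE 0.43, adjusted p = 3.38e-04) and fell by 2.53 in M-off (SE 0.43, adjusted p = 0.00107), from 423 ± 72.5 in littermates. Per1, a core clock gene, was 11.3 ± 7.39 in Z-off and 17.3 ± 3.70 in M-off against 114 ± 35.2 in littermates (log2 changes -2.26 and -1.94). Wee1 and Tef, also clock-controlled, changed by -1.61 and -1.66 in Z-off and by -1.58 and -1.30 in M-off. Circadian genes fell in 12 and rose in 3 of 28 in Z-off (14 and 3 adjusted over the list alone, adjusted p = 0.369, and adjusted p = 0.825 with an estimated correlation). They fell in 9 and rose in 2 in M-off (9 and 3 adjusted over the list alone, adjusted p = 0.823, and adjusted p = 0.956 with an estimated correlation), so neither list was called. Targets of NRF2 rose in 7 and fell in 3 of 34 in Z-off (8 and 3 adjusted over the list alone, adjusted p = 1.09e-05, and adjusted p = 0.381 with an estimated correlation). Gsta2, a glutathione transferase, rose from 482 ± 235 to 2158 ± 77.9 (log2 change 2.24, SE 0.29, adjusted p = 3.28e-04), Gclc rose by 1.34, and Slc7a11 and Fth1 fell by 1.01 and 0.72.

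Tubb2a, Elovl3, Mmd2 and Csad had the largest rises in Z-off over littermates, at 2.65 to 2.95, and Dbp, Alas1 and Mndal the largest falls after Usp2, at -2.36 to -3.02. In M-off the largest rises were those of Cyp2c37, Cyp2c55, Clec2d and Tubb2a, at 2.52 to 4.91, and Cyp2c39, Pctp and Aif1l fell most beside Usp2, at -2.57 to -3.69. All of these but Mmd2 passed with any single array left out. Cytosolic heat shock genes rose in 7 of 23 in M-off (8 adjusted over the list alone, adjusted p = 2.25e-07, and adjusted p = 0.621 with an estimated correlation). Fkbp4, Dnajb1, Bag3 and Cryab were at 0.68 to 1.06. Cholesterol synthesis genes rose in 4 and fell in 1 of 22 in M-off (6 and 1 adjusted over the list alone, adjusted p = 3.36e-05, and adjusted p = 0.621 with an estimated correlation). Pmvk, Cyp51 and Fdft1 were up by 0.56 to 1.00 and Lpin1 at -1.64. By limma, 500 genes were higher and 2496 lower in Z-off than in littermates (2996 of 12393), and 486 and 2757 in M-off (3243), with a median of all genes of -0.19 in both. After quantile normalization the counts were 591 and 988 in Z-off, 37.4% against 16.7% higher, and 555 and 1038 in M-off, 34.8% of them higher. Of the lists 8 were called in Z-off and 9 in M-off, all higher, among them proteasome, respiratory chain and mitochondrial ribosome genes in both groups. After quantile normalization only pancreas and adipose genes and NRF2 targets of the 8 lists stayed called in Z-off, and only cholesterol synthesis and heat shock genes of the 9 in M-off. It also added lists called lower, ER chaperones in Z-off and gluconeogenesis genes in M-off (adjusted p = 0.0454 for both).

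Single arrays ended further list calls of the off groups against littermates, with adjusted p = 0.0529 to 0.321. In Z-off these were pancreas and adipose (Z-off 1), cholesterol synthesis (Z-off 3 or littermate 1), bile acid (Z-off 3, littermates 2 or 3), female-type (Z-off 1, Z-on 2, M-on 1, littermates 1 or 3) and mitochondrial ribosome genes (Z-off 2 or M-on 1). In M-off they were ER chaperones (littermate 1), male-type (M-off 2, M-on 2, littermates 2 or 3) and ribosomal protein genes (M-off 2). Without dim genes, 6 of the 8 calls in Z-off ended, all but proteasome and NRF2 (adjusted p = 0.0958 to 0.160), and 4 of the 9 in M-off, those of male-type, respiratory chain, mitochondrial ribosome and ribosomal protein genes (adjusted p = 0.0603 to 0.150).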

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

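The tests of the 3 patterns weighed here were chosen after the results were seen. The counts over other splits of the arrays were planned.

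The on-off change differed between the Z and M lines in 76 genes, by the test of the difference itself. The largest differences in log2 change were 3.66 for Hspa1b, 2.77 for Gna14, 2.74 for Susd4 and 2.72 for Nox4 on the side of the Z line, and -6.20 for Cyp2c39, -3.53 for Cyp2c38, -3.48 for Vldlr and -3.02 for Mvk on the side of the M line. In Z-off minus M-off the log2 changes were 3.32 for Cyp2c39, 2.66 for Vldlr, -2.23 for Hspa1b, -1.77 for Gna14 and -1.68 for Susd4, of which Vldlr alone passed, so the off arrays carry part of these differences. These sizes depend on the added constant for dim genes, and with a constant of 1 only Nox4, Cyp2c39 and Vldlr of the 8 stayed called. Over 100 splits of the arrays drawn at random, the real one included, the highest count of another split was 29, against 76. Other splits mix Z and M arrays within a group, which widens the spread and favours low counts in them. The real grouping itself gave 11 genes with the replicate block, 18 with only the compared groups in the fit and 2 without array M-off 2. A chance split is therefore not excluded for the count of 76.

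The control probe sets, which enter no comparison, gave signals that followed the groups. The median poly-A signal was 59.0 on the 6 off arrays against 45.7 on littermate arrays, and the 18S 5' signal was 2297 on the 6 on arrays against 196 on littermate arrays.

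On and off arrays differed in 4838 genes in the Z line and 6239 in the M line. Over the 4838 genes called in the Z line, the on-off change of the M line was a median of 1.01 times that of the Z line (1.07, 1.01 and 0.969 with M-on 1, 2 and 3 alone), which argues against a change specific to the mutant protein as the source of most of them. The position of littermates, which drank no doxycycline, between M-off and M-on was taken over 3690 genes called in the Z line. These genes also changed by more than 0.5 log2 units in the M line. The median position was 0.5835 of the way from M-off to M-on. It was 0.557 to 0.621 with each array of the 3 groups left out or alone in its group and 0.491 after quantile normalization. This cannot decide on doxycycline alone, because littermate and M-on arrays also differed in median poly-A signal (45.7 and 4.50). Choosing genes by the size of their M-line change can also lower the position. Poly-A controls, which match no mouse transcript, were -1.942 log2 units apart in on minus off arrays, with no overlap of arrays. A difference in preparation may therefore lie behind a part of the on-off changes that was not measured. Expression of either human protein, as the design has it, and doxycycline stay open beside preparation, because all of these follow the on and off groups. Time of day or feeding stays open too. Members of the circadian list changed between on and off in both lines, though the list was called in neither line before quantile normalization. The labels used here give no time of collection.

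Arrays labelled M-on 1 and 2 differed from the other arrays in sex-linked transcripts. Xist on its brightest probe set was 15.47 times (M-on 1) and 3.042 times (M-on 2) the highest of the other 13 arrays, and 76.9 and 16.6 times on another probe set, but 4.57 and 0.791 times on a dim one. The higher of their Eif2s3y signals was 0.03088 of the lowest on another array, which argues against a hormonal change in male liver, since such a change leaves the Y chromosome in place. A candidate explanation is therefore that female mice, or their RNA, gave these arrays, against the design's males. M-on 2 had 0.197 of the Xist signal of M-on 1, so a lower yield stays open. Its Eif2s3y signal (1.3) and female-type median (1.63, against 1.78 on M-on 1) argue against much male RNA. The state of M-on 3 is open too, with Eif2s3y at 42.1, under the 105.3 or more of the other 12 arrays, but no high Xist signal.

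Cholesterol synthesis genes were lower in Z-on than in M-on. The Z-on mean of the list's per-array medians lay -1.056 log2 units from that of the 9 arrays of the off groups and littermates (-0.87 ± 0.38 against 0.18 ± 0.22, n = 3 and 9). The exact two-sided permutation p was 0.00455, the smallest that 220 splits allow, for a pattern first seen in these arrays. All 3 Z-on arrays lay below these 9, which argues against female mice among the M-on arrays as the whole cause. The M-on arrays lay above the 9 (0.72 ± 0.037 against at most 0.52), across the same difference in control signals. A shift common to both on groups cancels in Z-on minus M-on and in the interaction, so neither can test such a preparation. The list's interaction median was -1.258 before that of all genes is subtracted. A preparation that differed between Z-on and M-on cannot be told apart from the groups it follows, as their poly-A signals were -0.1527 log2 units apart without overlap of arrays. Time of day or feeding could not be told apart from an effect of the Z protein, because the circadian list also differed, by a median of 0.3517 before that of all genes is subtracted, and the labels used here give no time of collection.

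For contrasts of 3 arrays with 3 there are 10 splits, too few for a share under 0.05. The real count of genes was the highest in 1 split, the real one, in every case. It was 4838 in Z-on minus Z-off (highest other split 1), 6239 in M-on minus M-off (0), 639 in Z-on minus M-on (26), 1480 in Z-on minus littermates (1), 2958 in M-on minus littermates (4), 17 in Z-off minus M-off (1), 2996 in Z-off minus littermates (1) and 3243 in M-off minus littermates (1). For the number of lists called, as many were called in 4 splits for Z-on minus Z-off (11, highest other 15), 6 for M-on minus M-off (8, 14), 2 for Z-on minus M-on (12, 13), 1 for Z-on minus littermates (13, 9), 3 for M-on minus littermates (10, 15), 5 for Z-off minus M-off (9, 11), 6 for Z-off minus littermates (8, 11) and 1 for M-off minus littermates (9, 8). For the interaction 11 of 100 splits called as many lists as the real 12, with a highest of 17, so a chance split is not excluded for that number of lists.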

How the results depend on the processing

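Constants of 1 and 64, leaving out 2 M-on arrays together, and quantile normalization for the lists were chosen after the data were seen, and the other alternatives were planned. Counts with each array left out were 3729 to 5316 for Z-on minus Z-off, 5346 to 6295 for M-on minus M-off, 76 to 1677 for Z-on minus M-on, 932 to 1873 for Z-on and 1903 to 3155 for M-on minus littermates, 6 to 51 for Z-off minus M-off, 2046 to 3454 for Z-off and 2305 to 3656 for M-off minus littermates, and 2 to 1030 for the interaction, with 86 to 100 lists (92 with all arrays). Leaving out M-on 1 gave the highest counts of 7 of the 9 contrasts. A fit of only the compared groups takes the spread from these groups alone and has fewer residual degrees of freedom. Its counts were 18 for Z-on minus M-on, 956 for Z-on and 888 for M-on minus littermates, 37 for Z-off minus M-off and 18 for the interaction. The count rose for Z-on minus Z-off (5127 against 4838) and for Z-off minus M-off, and fell for the other contrasts. The parts of spread and degrees of freedom were not separated. All probe sets, which are more than the genes, gave 8155 for Z-on minus Z-off, 10530 for M-on minus M-off, 1012 for Z-on minus M-on, 2782 for Z-on, 5207 for M-on, 4843 for Z-off and 5283 for M-off minus littermates. Quantile normalization, which removes differences between array distributions, gave 3211 for Z-on minus Z-off, 1579 for Z-off and 1593 for M-off minus littermates. It reversed Serpina1b (0.02475), Serpina1c (0.03451), Apoa2 (0.148) and Alb (0.06289) in Z-on minus littermates and Serpina1b (0.1146) in M-on minus littermates. It left 58 lists called, 50 of them among the 92, and turned the medians of hepatocyte secretory genes to 0.07346 in Z-on minus Z-off, 0.01193 in M-on minus M-off and 0.05513 in Z-on minus littermates, where the alpha1-antitrypsin family came to 0.03472. Without dim genes 72 of the 92 stayed called. With an estimated correlation 0 lists were called.

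An intensity trend with robust spread gave 26 genes for Z-off minus M-off. Array weights, 0.292 for M-on 1 and 1.95 for M-on 2, gave 1858 for Z-on minus M-on, 231 for Z-off minus M-off and 1157 for the interaction. The cause was not tested for either. A constant of 1, which lets dim signals spread, gave 144 for Z-on minus M-on, 976 for Z-on minus littermates, 27 for Z-off minus M-off and 23 for the interaction, and a constant of 64 gave 135 for the interaction. Without arrays M-on 1 and 2 the counts were 1272 for Z-on minus M-on, 30 for Z-off minus M-off and 811 for the interaction. The medians of the male-type genes became -0.5089 in Z-on minus M-on (adjusted p = 0.00473), 0.2387 in M-on minus littermates and -0.3839 in the interaction, and those of the female-type genes 0.3038 in Z-on minus M-on and -0.003908 in M-on minus littermates. Without M-on 2 and 3 the counts were 69 for Z-on minus M-on, 1153 for M-on minus littermates, 30 for Z-off minus M-off and 50 for the interaction, and the proteasome medians became 0.06554 in Z-on minus M-on and 0.04198 in the interaction. The lone M-on array is there assumed to vary like the other groups.

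Replicate numbers did not pair the arrays, as the correlations of arrays with the same number ran from -0.173 to 0.066 over 30 pairs, and with the replicate number as a block only the interaction count moved by more than 1.5 times, to 11. Of 343 changes of named genes, quantile normalization kept 311 on their side of the threshold, a constant of 1 kept 296, the block 319 and the fit of only the compared groups 278. Leaving out each array kept 4695 and ended 437 of these comparisons.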

Other observations

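The groups and tests in this part were chosen after the data were seen, apart from the gene lists. Genes higher or lower in one group than in each of the other 4, called in all 4 contrasts, numbered 24 higher and 43 lower in Z-on, 66 and 291 in M-on, 4 and 1 in Z-off, 3 and 5 in M-off and 90 and 34 in littermates. In 20 simulated sets without effects there were at most 0. Those sets had no group differences at all and independent genes. They therefore say nothing on differences in preparation or sex among the arrays. The M-on counts depended on which arrays were kept, as 24 of the 66 and 266 of the 291 stayed without arrays M-on 1 and 2, and 8 and 5 stayed without M-on 2 and 3. With a constant of 1 in place of 16, 2 and 22 of the Z-on, 13 and 68 of the M-on and 44 and 26 of the littermate genes stayed, and after quantile normalization 13 and 37, 52 and 284, and 27 and 24. Those of Z-on began with Rgs16, Sema3e, Bach2 and Ccn2 on the higher side, at least 1.89, 1.76, 1.15 and 1.03 log2 units above each other group, none of which stayed with a constant of 1. On the lower side were 9 genes of cholesterol synthesis, Mvk, Fdps, Cyp51, Sc5d, Sqle, Fdft1, Dhcr7, Tm7sf2 and Pmvk, by at least -0.71 (Pmvk) to -1.83 (Mvk), of which all but Sc5d and Tm7sf2 stayed with it, though the size for Mvk depends on the constant. The macrophage transcripts C1qa and C1qc and the immunoproteasome subunit Psmb10 were also lower in Z-on than in each other group, Psmb10 not with a constant of 1.

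The family of regulators of G protein signalling, to which Rgs16 belongs, was looked at in both lines. Of 16 measured RGS genes 8 rose in Z-on minus Z-off and 8 in M-on minus M-off, and none fell (8 and 9 adjusted over the list alone), without a call for the list (adjusted p = 0.117 and 0.296, and 0.757 and 0.781 with an estimated correlation). After quantile normalization 5 and 4 rose. Targets of the integrated stress response rose in 15 and fell in 3 of 30 in Z-on and rose in 15 and fell in 2 in M-on (15 and 4, and 16 and 3, adjusted over the list alone), again without a call (adjusted p = 0.934 and 0.563, and 0.960 and 0.825 with an estimated correlation). After quantile normalization 6 rose and 3 fell in Z-on, and 11 rose and 2 fell in M-on.

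Genes called in both lines included 3230 higher and 544 lower in each, against 1485 and 115 under independence. Those called in both numbered 3806, and 2287 after quantile normalization. Across genes, which are not independent replicates, the on-off changes of both lines had a Pearson r of 0.732 and a Spearman rho of 0.760, and a Pearson r of 0.676 after quantile normalization.

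Some transcripts separated array M-on 1 from M-on 2 and 3. Malat1, a nuclear long noncoding RNA, read 163.5 on M-on 1 and 3.7 and 0.9 on M-on 2 and 3. Ube3a read 245.7, 17.7 and 19.9, and Mbnl1 read 654.5, 81.1 and 108.7. Relative to the littermate mean, the median of male-type liver genes was -1.30, -1.42 and 0.29 on M-on 1, 2 and 3, and that of female-type genes was 1.78, 1.63 and 0.05.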
